A study of Gallus gallus with 10 samples.

How the data were processed

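RNA was measured by poly(A) RNA-seq in cranial neural folds of chick embryos, in 10 libraries that the labels assign to 2 groups. The 5 libraries of the control group came from embryos given a control morpholino and the 5 libraries of the other group from embryos given an NSD3 morpholino. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, each library was a pool of homogenised neural folds from 12 embryos, made from 60 embryos per condition, so the replicates are separate pools of embryos. The labels do not tie replicate numbers to shared days or batches, and no batch label was used here.

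The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled for library size) for 19168 genes in each library. They also deposited a table of 674 genes with a log2 fold change, an adjusted p-value, a mean count that is not a whole number, and the group means and standard deviations of the FPKM. Per the submitters' processing notes, Trimmomatic 0.32, STAR 2.5.3a and DESeq2 1.28.1 were used with the chick genome build GRCg6a (galGal6). The role of each tool, the counting tool and the gene annotation release are not given in the sources used here. The authors' table lists genes with an adjusted p-value up to 0.0499. It also carries columns on neural crest from another published data set, and the groups compared in that data set are not given in the sources used here. The kit named in the labels preserves strand, but whether the counting used strand is not given, so overlapping and antisense genes are treated as uncertain.

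Gene names were taken from the deposited FPKM table, which pairs 12611 Ensembl identifiers with a symbol of their own and a further 1643 with a protein database symbol. The remaining 4914 identifiers carry no symbol. A RefSeq gene table for assembly GRCg7b matched 0 of those and its coordinates were not used, since its build differs from that of the files. No coordinates are printed.

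The analysis was run in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. FPKM values are not counts, so tests were made on log2(FPKM + 0.5). Genes with a mean FPKM of at least 1 over the 10 libraries were kept, which left 11935. A linear model with 1 term for the group was fitted with limma with a mean-variance trend. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called higher or lower. Log2 fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Changes written as a number of folds are ratios of the group means of FPKM, except the count of genes past 2-fold, which is on the fitted scale. For NSD3 alone an exact permutation test over the 252 arrangements of the libraries was added.

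The model, the filter, 30 gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The lists covered the neural plate border, neural crest specification, neural crest EMT and migration, neural tube progenitors, non-neural ectoderm, preplacodal ectoderm, head mesenchyme and mesoderm, notochord and floor plate, endoderm, blood and endothelium, HOX genes and W-linked genes. They also covered targets of WNT, BMP and TGFb, FGF, Notch, hedgehog and retinoic acid, p53 targets and apoptosis, cell cycle, histone genes, ribosomal proteins, mitochondrial respiration, glycolysis and hypoxia, cholesterol synthesis, stress response, immediate early genes, interferon response, extracellular matrix and laminins, and H3K36 and SET domain enzymes. The 28 lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. The lists are short and hand-made, and some genes stand in several of them.

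The genes named in the text follow that rule. It takes NSD3, the 12 largest rises and 12 largest falls among called genes with a symbol and no overlap between groups, up to 4 members of each described list with the smallest adjusted p, any member of the neural plate border and neural crest specification lists, and the 3 genes with the smallest adjusted p per direction of the authors' table. MDM2, BAK1, SOX2, FOS and JUN were named after their values were seen. Some genes that the rule takes are not reported here.

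Read totals were not used here. FPKM steps of low genes gave the factor by which each library had been scaled, relative to the geometric mean of the libraries. This factor is called relative depth here and need not equal the ratio of read totals. On 5 simulated libraries this method erred by at most 0.004% over 12000 genes. The model was tested on simulated data of 11935 genes with the real means and fitted spreads, in 5 simulations with 200 genes changed in each. In the comparison of NSD3 morpholino with control, 56% of genes changed by 0.5 on the log2 scale were recovered, 91.2% at 1, 99.2% at 2 and 100% at 3. Among all calls, 4.1% were false. A list shifted by -0.3 was called in 5 of 5 simulations, and 1 of 135 tests of other lists was called. These simulated genes vary independently, so they do not test lists whose members vary together.

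Every count was recomputed with pseudocounts of 1 and 0.1, without a filter, with a minimum mean FPKM of 5, with 3 other scalings, without the trend, with robust variance, with array quality weights, with the replicate number as a block, at an adjusted p under 0.01, and without each library in turn. Alternatives added after the data were seen were leaving out control replicates 4 and 5 together, and covariates for the mean immediate early and W-linked levels. The comparison was also repeated on 100 of the 126 possible splits of the 10 libraries into groups of 5, drawn with a fixed seed.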

Results

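Cranial neural folds, the dorsal head tissue that gives rise to neural crest cells, were profiled by RNA-seq in chick embryos after an NSD3 morpholino or a control morpholino. NSD3 is a SET domain histone methyltransferase, and morpholinos are antisense oligomers that block translation or splicing of their target RNA. The labels do not say which of these the NSD3 morpholino blocks. Embryos were electroporated on both sides at Hamburger-Hamilton stage 4 to 5 with 0.5 mM morpholino and 300 ng/µL carrier DNA, and folds were taken at 5 to 7 somites. Each group had 5 libraries, each a pool of 12 embryos. Relative depth ran from 0.887 in NSD3 morpholino replicate 3 to 1.295 in NSD3 morpholino replicate 1. Between 16238 and 16638 genes had an FPKM above 0 in each library. No library pair within a group had identical deposited FPKM, given to at most 3 decimals, in more than 0.142% of tested genes, so all libraries were counted as separate samples.

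The targeted transcript was compared first. NSD3 stood at 22.9 ± 2.29 FPKM (SD, n = 5) in controls and 17.9 ± 1.36 FPKM (SD, n = 5) with the NSD3 morpholino. All 5 NSD3 morpholino pools lay below all 5 control pools, with an exact permutation p of 0.007937 (two-sided), the smallest the design allows. The fitted log2 fold change was -0.34 (SE 0.0838), with a limma adjusted p of 0.055 that missed the threshold over all genes. In the authors' deposited table, NSD3 had a log2 fold change of -0.35 and an adjusted p of 0.00439. Without control replicates 4 and 5, which had the highest NSD3 values, the log2 fold change was -0.24 with an adjusted p of 0.117. A morpholino that blocks translation need not lower its target's RNA, so the level checks the labels but does not measure the loss of protein.

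The next question was which genes differed in level when NSD3 was targeted. CDKN1A, EDA2R and TNFRSF10B, members of the p53 target list, were among the 12 largest rises of named genes without overlap. CDKN1A, which encodes the cell cycle inhibitor p21, rose 10.7-fold from 2.64 ± 0.962 to 28.2 ± 4.62 FPKM (SD, n = 5 each). Among the falls, NYX, which encodes the leucine-rich repeat protein nyctalopin, fell from 10.8 ± 3.81 to 0.600 ± 0.0992 FPKM. COQ9, a factor of coenzyme Q synthesis, fell from 12.9 ± 1.41 to 5.42 ± 0.922 FPKM, and the ribosomal protein paralog RPL22L1 fell from 196 ± 15.4 to 98.6 ± 13.7 FPKM. In all, 179 genes were higher and 122 lower of 11935 tested by limma, and 2157 had an unadjusted p under 0.05. Of the called genes, 46 rose and 8 fell by at least 2-fold on the fitted scale. Groups did not overlap for 6.04% of the tested genes, against 0.79% by chance. With FPKM rescaled to the same total, 123 genes were higher and 172 lower, so the share of rises went from 59.5% to 41.7% of calls. Rescaling by median ratios changed none of the 301 calls, so the deposited values already lay close to that scale. Leaving out 1 library gave between 69 and 211 genes higher and between 32 and 151 lower, with both lowest counts without NSD3 morpholino replicate 2. The higher count moved by over 1.5 times without control replicates 1 (115) or 4 (107) and NSD3 morpholino replicates 2 (69), 3 (85), 4 (81) or 5 (93). The lower count did so without control replicates 1 (72), 2 (61) or 4 (58) and NSD3 morpholino replicates 1 (70), 2 (32), 3 (67), 4 (44) or 5 (43).

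**Figure D1:**
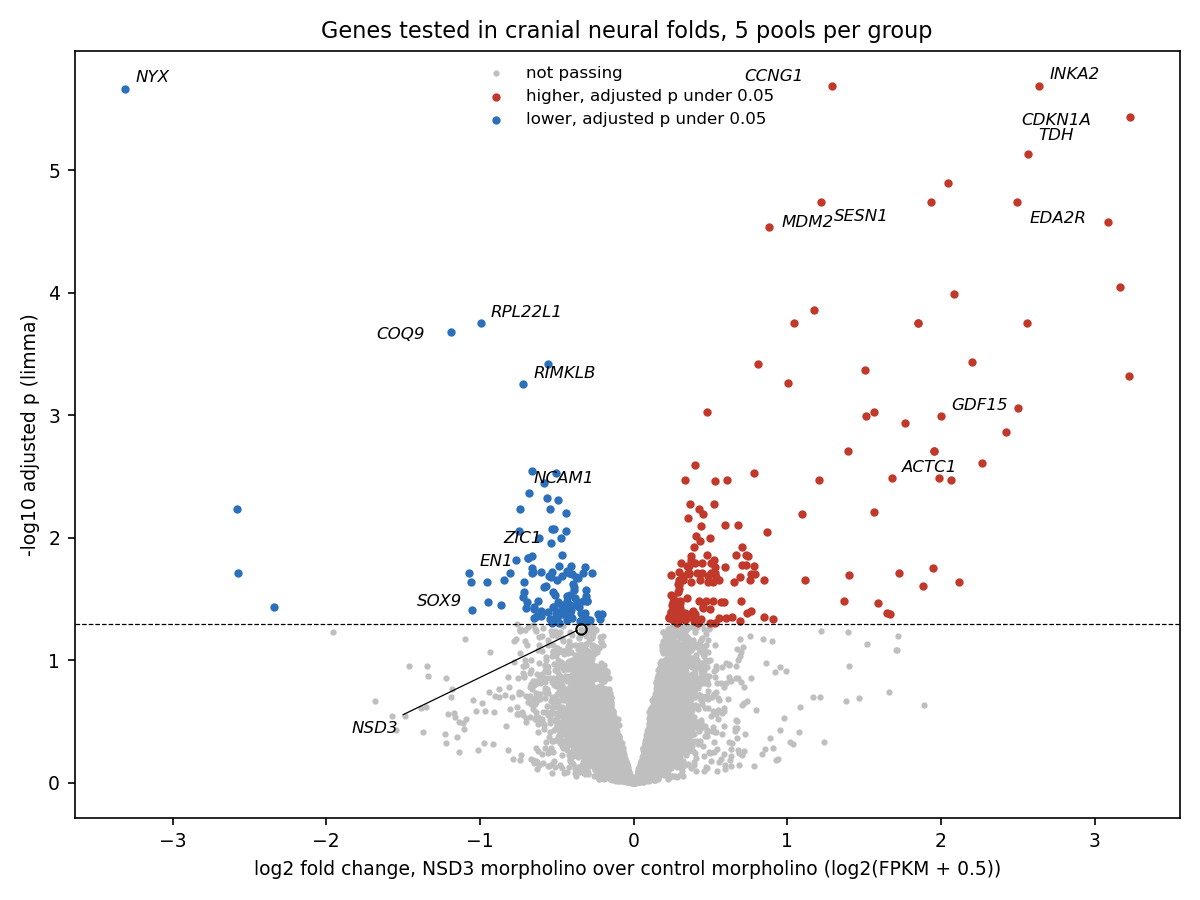
Log2 fold change of NSD3 morpholino over control (horizontal axis, on log2(FPKM + 0.5)) against -log10 of the limma adjusted p (vertical axis) for 11935 genes, with 5 pools per group and a dashed line at 0.05. The 179 genes higher are red, the 122 genes lower are blue, CDKN1A lies at 3.23, NYX at -3.31, and NSD3 lies just under the line.

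The 12 largest rises among named genes without overlap were CDKN1A, INKA2, TDH, EDA2R, TNFRSF10B, BLVRA, GDF15, GAS6, ACTC1, gga-mir-20b, SNORD18 and gga-mir-34a. INKA2 rose 8.26-fold to 10.8 ± 1.87 FPKM and TDH, which encodes threonine dehydrogenase, from 1.85 ± 0.501 to 13.3 ± 2.31 FPKM. BLVRA, a biliverdin reductase, rose 5.04-fold, GDF15, a secreted stress-induced cytokine, 5.48-fold, and GAS6, a ligand of TAM receptor kinases, 4.49-fold. ACTC1, the cardiac muscle actin, rose 4.24-fold. The microRNA gene gga-mir-34a rose 3.00-fold from 9.35 ± 2.90 FPKM. The values of gga-mir-20b, SNORD18 and gga-mir-34a are uncertain, because poly(A) libraries do not capture mature short RNAs and their reads can come from overlapping genes. The call of gga-mir-20b ended when any 1 of 8 libraries was left out, and that of SNORD18 when any 1 of 7 was.

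The 12 largest falls among named genes without overlap were NYX, COQ9, EN1, PRDM12, RPL22L1, G0S2, SOX9, POU4F1, AAMDC, DISP3, ZIC1 and RIMKLB. Of the 179 genes higher and 122 lower, 150 and 107 had a symbol other than a placeholder identifier. Larger changes of genes without such a symbol, or with overlapping groups, are not ranked here. EN1, a homeobox gene of the midbrain-hindbrain region, fell from 9.02 ± 1.87 to 4.08 ± 1.18 FPKM. PRDM12 fell from 6.45 ± 2.24 to 2.77 ± 0.731 FPKM and POU4F1 from 3.57 ± 0.623 to 1.78 ± 0.612 FPKM, both transcription factor genes of sensory neuron development. RIMKLB fell from 23.3 ± 2.19 to 13.9 ± 0.970 FPKM, DISP3 from 11.6 ± 1.42 to 6.56 ± 1.64 FPKM, AAMDC from 9.82 ± 2.23 to 5.22 ± 0.985 FPKM and G0S2 from 2.01 ± 0.390 to 0.812 ± 0.303 FPKM. The calls of NYX, COQ9, RPL22L1, RIMKLB and ZIC1 held without each library in turn. Those of EN1, DISP3, G0S2, PRDM12, AAMDC, POU4F1 and SOX9 were lost without some single libraries, with adjusted p up to 0.0995.

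**Figure D2:**
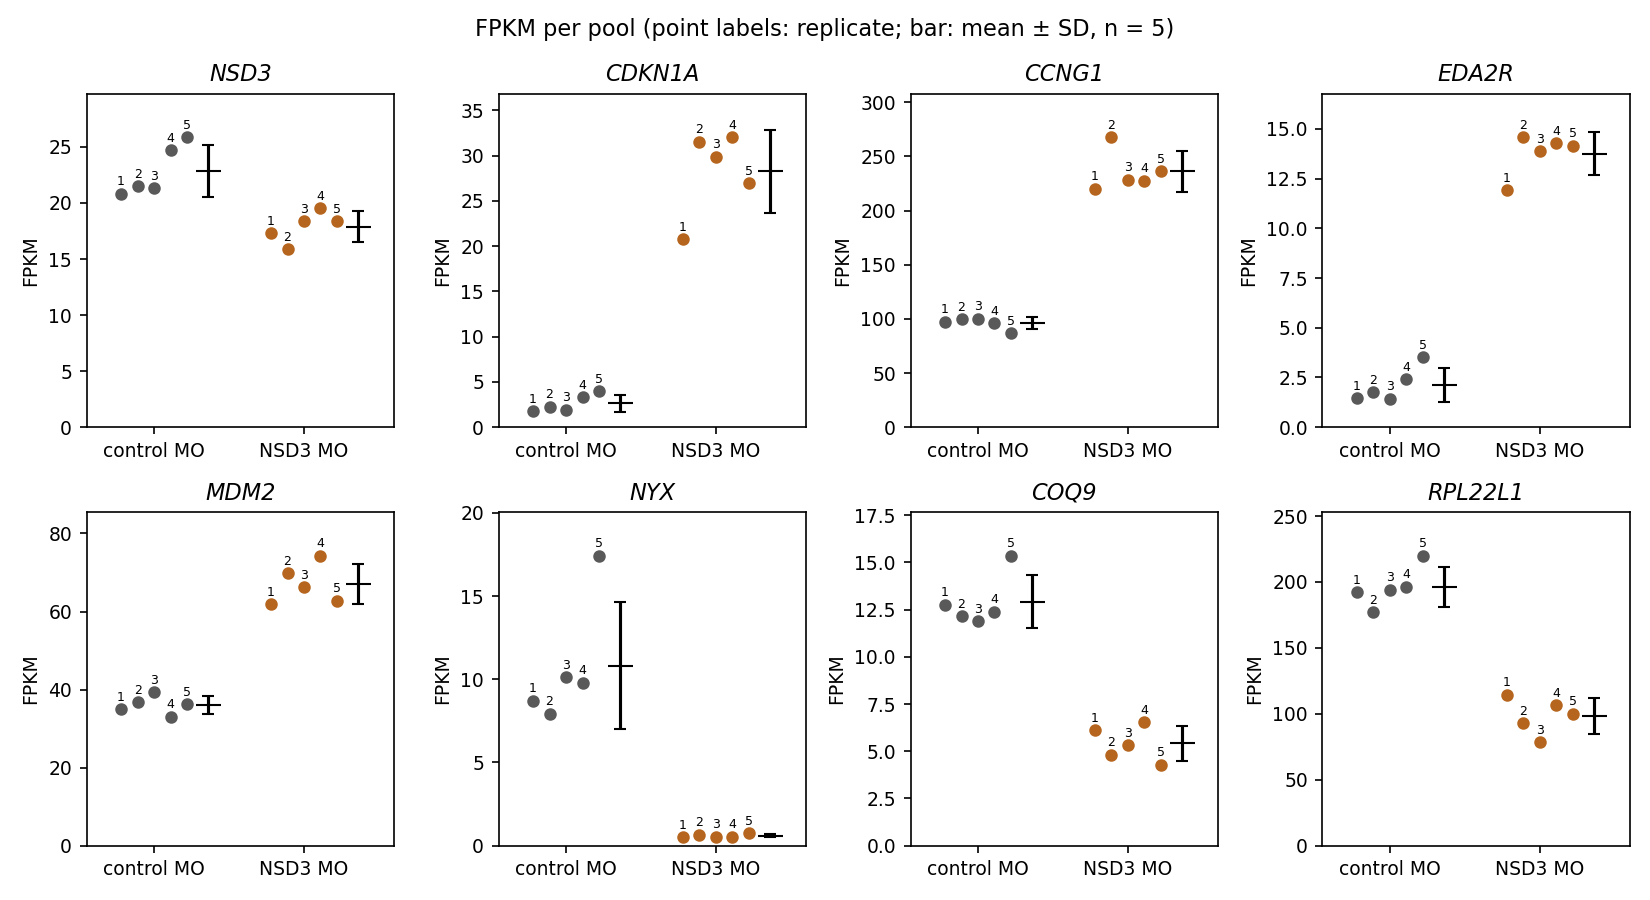
FPKM of NSD3, CDKN1A, CCNG1, EDA2R, MDM2, NYX, COQ9 and RPL22L1 in each pool (points numbered by replicate), with bars for mean ± SD (n = 5). Each vertical axis starts at 0, and for all 8 genes the groups do not overlap.

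Among 35 tested members of the list of p53 targets and apoptosis genes, 7 rose, 0 fell and 28 did not pass. Adjusted over the list alone, 8 rose and 2 fell. CCNG1, a p53-induced cyclin, rose from 96.0 ± 5.41 to 236 ± 18.7 FPKM. SESN1, a stress-induced sestrin, rose from 14.9 ± 1.72 to 35.2 ± 2.84 FPKM, and the death receptor genes EDA2R and TNFRSF10B rose 6.49-fold and 4.67-fold. MDM2, the p53 ubiquitin ligase, rose from 36.1 ± 2.30 to 67.0 ± 5.16 FPKM, and BAK1, an apoptosis effector, from 67.7 ± 4.98 to 97.6 ± 9.58 FPKM. The list was higher than other genes by camera, with an adjusted p of 0.00141, a median log2 fold change of 0.07 and a mean of 0.37, so a few members carried it. The adjusted p = 0.0736 with an estimated correlation missed the threshold. The estimate for this list was 4e-04, below the preset 0.01, so a higher correlation among its members did not account for the miss. By fry, which asks whether the list's own genes move one way, the adjusted p was 2.51e-05. The mean level of the list lay between 0.165 and 0.218 above the overall mean in the NSD3 morpholino pools and below it in all 5 control pools, on the log2 scale.

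Several transcription factor genes of neural crest specification were lower. SOX9 fell from 54.1 ± 11.8 to 28.1 ± 7.20 FPKM, TFAP2B from 61.2 ± 11.7 to 38.3 ± 3.86 FPKM and POU4F3 from 37.7 ± 5.71 to 23.3 ± 4.63 FPKM. Of 26 tested members of the list, these 3 fell, 0 rose and 23 did not pass, and 7 fell when adjusted over the list alone. FOXD3 averaged 407 ± 183 FPKM in controls and 238 ± 55.5 FPKM with the NSD3 morpholino (adjusted p 0.133 by limma). SOX10 averaged 15.7 ± 9.61 and 8.70 ± 3.22 FPKM (adjusted p 0.279), SNAI2 268 ± 49.3 and 209 ± 54.0 FPKM (adjusted p 0.322), and CSRNP1 71.6 ± 12.4 and 49.2 ± 8.28 FPKM (adjusted p 0.0576). The list was lower by camera, with an adjusted p of 0.00015 and a median log2 fold change of -0.21, and adjusted p = 0.589 with an estimated correlation. In control replicate 5, FOXD3 stood at 731 FPKM and the list's mean level at 0.599, the highest of the 10 pools. As small a camera p came from 13 of 100 splits of the libraries. Without control replicates 4 and 5, the camera adjusted p was 0.137 (range over 24 alternatives 3.77e-05 to 0.137), and the SOX9 log2 fold change was -0.80 with a limma adjusted p of 0.0852. In that setting 1 member was called lower, TFAP2B (-0.55, limma adjusted p 0.0097), and 1 was called higher, ID1 (0.55, limma adjusted p 0.0283). With all libraries ID1 had a log2 fold change of 0.35 and a limma adjusted p of 0.215. The call of POU4F3 ended when any 1 of 5 libraries was left out, with an adjusted p up to 0.0807.

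At the neural plate border, ZIC1, a zinc finger transcription factor gene, fell from 17.9 ± 2.19 to 10.4 ± 2.19 FPKM. Of 14 tested members of the list 1 fell and 13 did not pass, and 5 fell when adjusted over the list alone. PAX7 averaged 26.2 ± 0.727 FPKM in controls and 20.3 ± 3.75 FPKM with the NSD3 morpholino (adjusted p 0.107), TFAP2A 113 ± 10.9 and 89.3 ± 13.3 FPKM (adjusted p 0.111), ZIC2 355 ± 73.0 and 260 ± 22.2 FPKM (adjusted p 0.0865) and MSX1 340 ± 114 and 250 ± 37.8 FPKM (adjusted p 0.305), all by limma. Without control replicates 4 and 5 the log2 fold change went from -0.39 to -0.05 for MSX1 and from -0.43 to -0.23 for ZIC2. It went from -0.38 to -0.36 for PAX7 and from -0.34 to -0.25 for TFAP2A. Other members turned positive in that setting: PAX3 went from -0.03 to 0.35, DLX5 from -0.07 to 0.13, BMP4 from -0.13 to 0.11 and GBX2 from -0.17 to 0.03. With all libraries 2 members had positive log2 fold changes, GATA3 (0.46, limma adjusted p 0.198) and MSX2 (0.08, limma adjusted p 0.886). Without control replicates 4 and 5 these 2 stood at 0.64 and 0.29. The list was lower by camera with an adjusted p of 0.00686, and adjusted p = 0.759 with an estimated correlation. Its camera adjusted p over 24 alternatives ran from 0.000966 to 0.591, at 0.0691 without control replicate 5 and 0.591 without control replicates 4 and 5, whose list levels of 0.365 and 0.433 were the highest of the 10 pools.

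Among neural tube progenitor genes, the neural cell adhesion gene NCAM1 fell from 36.8 ± 3.12 to 26.0 ± 1.52 FPKM and EN1 fell as given above. Of 29 tested members these 2 fell, 0 rose and 27 did not pass, and 4 fell when adjusted over the list alone. The Notch ligand gene DLL1 averaged 15.5 ± 4.71 and 8.87 ± 1.61 FPKM (adjusted p 0.057), LMX1B 67.2 ± 7.66 and 54.6 ± 2.38 FPKM (adjusted p 0.0694), and the pan-neural gene SOX2 88.8 ± 15.3 and 84.4 ± 5.07 FPKM (adjusted p 0.829), by limma. The list was lower by camera with an adjusted p of 2.97e-05 and a median log2 fold change of -0.24, and adjusted p = 0.589 with an estimated correlation. Without control replicates 4 and 5, where its level was 0.284 and 0.549, the adjusted p was 0.121 (range over 24 alternatives 1.04e-06 to 0.121) and the median -0.10. As small a camera p came from 13 of 100 splits of the libraries. The NCAM1 call held there, with a log2 fold change of -0.44 and an adjusted p of 0.0125, and the EN1 call did not, with -0.97 and an adjusted p of 0.0575.

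**Figure D3:**
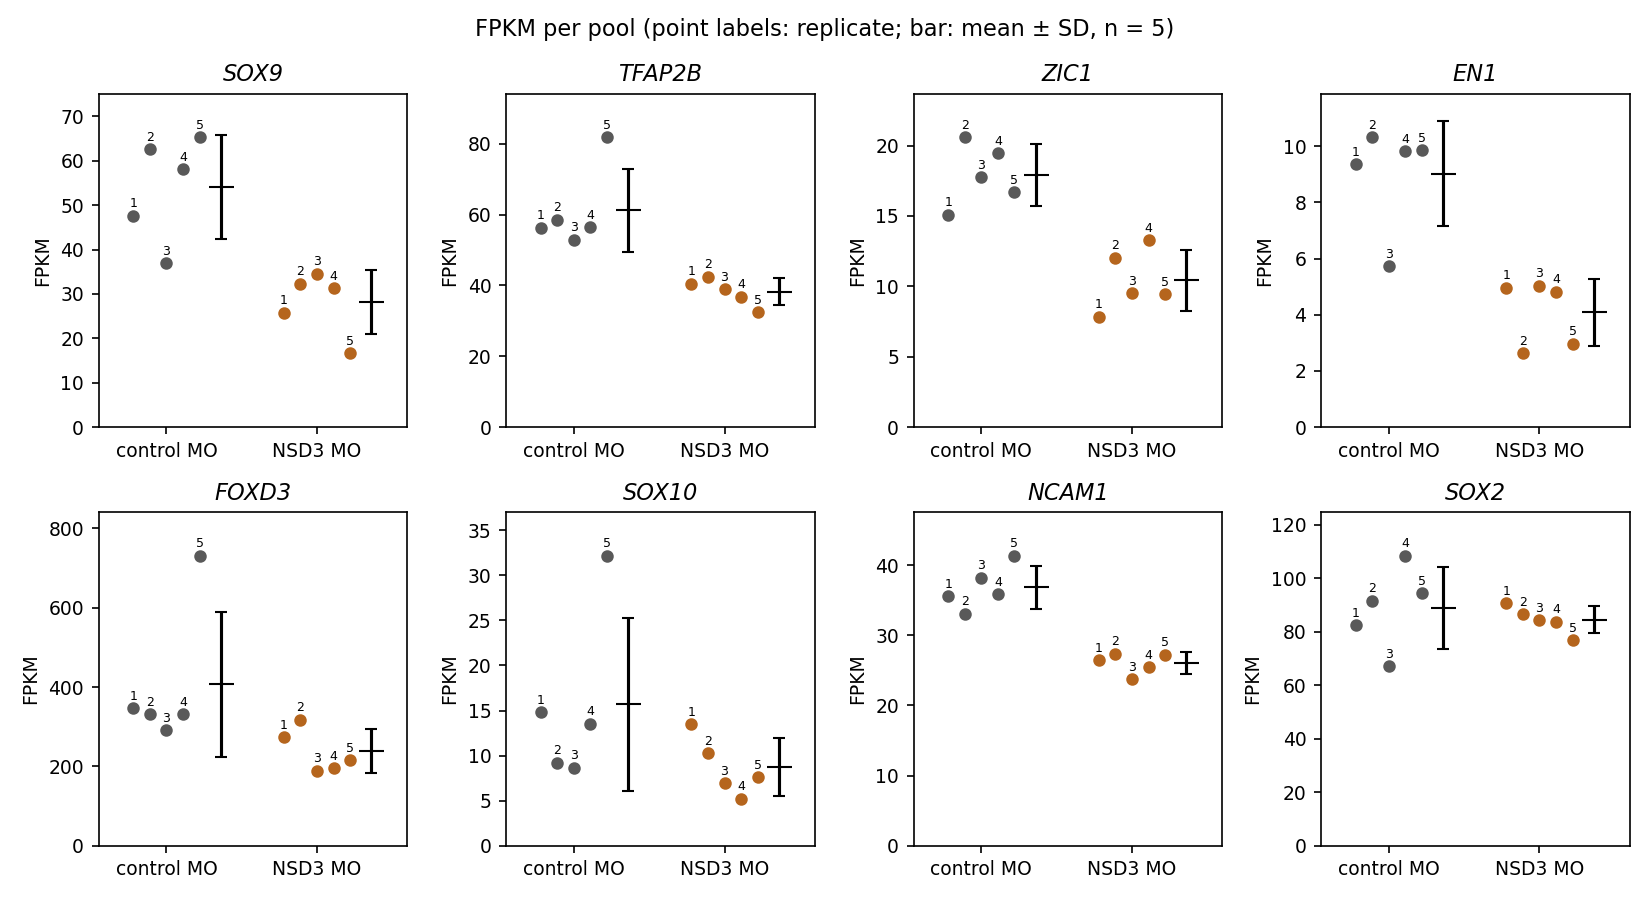
FPKM of SOX9, TFAP2B, ZIC1, EN1, FOXD3, SOX10, NCAM1 and SOX2 in each pool (points numbered by replicate), with bars for mean ± SD (n = 5). Each vertical axis starts at 0, the groups do not overlap for SOX9, TFAP2B, ZIC1, EN1 and NCAM1, and control replicate 5 is highest for FOXD3 at 731 FPKM.

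Genes of matrix and migration went both ways. FN1, the gene of the matrix protein fibronectin, rose from 102 ± 6.48 to 164 ± 30.8 FPKM, while the cadherin gene CDH7 fell from 5.88 ± 0.614 to 3.95 ± 0.558 FPKM and the collagen gene COL5A1 from 8.34 ± 1.23 to 5.65 ± 0.640 FPKM. Of 42 tested members of the neural crest EMT and migration list, FN1 rose, CDH7 and COL5A1 fell and 39 did not pass, and adjusted over the list alone 2 rose and 5 fell. The list was lower by camera with an adjusted p of 0.0197, and adjusted p = 0.589 with an estimated correlation. Its camera adjusted p was 0.0509 without control replicate 5 (range over 24 alternatives 0.00325 to 0.0509). In the extracellular matrix and laminins list, FN1 and HAPLN1, a hyaluronan link protein gene, rose and COL5A1 fell, and 27 of 30 members did not pass. Adjusted over that list alone, 3 rose and 2 fell, and the list itself was not called (adjusted p 0.826). The calls of CDH7 and COL5A1 each ended when any 1 of 7 libraries was left out, with adjusted p up to 0.103, and that of HAPLN1 when any 1 of 2 was (0.0575).

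Genes of cholesterol synthesis and ribosomal proteins were also compared as lists. SREBF2, a transcription factor gene that controls cholesterol synthesis, fell from 21.1 ± 1.85 to 15.8 ± 1.45 FPKM. Of 26 members of the cholesterol synthesis list 2 fell and 24 did not pass, and 2 fell when adjusted over the list alone. The call of SREBF2 ended when any 1 of 8 libraries was left out, with an adjusted p up to 0.0817. The cholesterol synthesis list was lower by camera with an adjusted p of 0.00141, and adjusted p = 0.589 with an estimated correlation. Without control replicates 4 and 5 it had 7 members lower and 1 higher, a median log2 fold change of -0.25 against -0.14, an adjusted p of 8.11e-07 (up to 0.0212 in other alternatives), and adjusted p = 0.229 with an estimated correlation. Among 63 ribosomal protein genes RPL10A fell from 374 ± 43.1 to 274 ± 7.08 FPKM, RPL3 from 660 ± 50.2 to 529 ± 16.2 FPKM and RPL12 from 416 ± 52.2 to 324 ± 12.2 FPKM, and 60 did not pass. The same 3 fell adjusted over the list alone, and the list's median log2 fold change was -0.06. Its adjusted p was 0.00141, and adjusted p = 0.759 with an estimated correlation. The ribosomal list had an adjusted p of 0.209 without control replicate 5 and 0.79 without control replicates 4 and 5 (range over 24 alternatives 3.03e-05 to 0.79). The call of RPL12 ended when any 1 of 7 libraries was left out, with an adjusted p up to 0.0974, and that of RPL3 when any 1 of 2 was (0.0583). Whether reads of ribosomal protein genes also match other, similar sequences was not checked here, so their FPKM is uncertain.

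Of 41 tested members of the list of H3K36 and SET domain enzymes, EZH1 fell from 7.58 ± 0.438 to 5.77 ± 0.255 FPKM and 40 did not pass. Adjusted over the list alone 2 fell, EZH1 and NSD3 itself. The list, which includes NSD3, was lower by camera with an adjusted p of 0.0359, and adjusted p = 0.607 with an estimated correlation. Of 9 mesoderm and head mesenchyme genes FOXC2 rose from 4.47 ± 0.940 to 7.86 ± 1.27 FPKM and 8 did not pass, while 3 rose when adjusted over the list alone. That list was higher by camera with an adjusted p of 0.0487, and adjusted p = 0.589 with an estimated correlation. The call of EZH1 ended when any 1 of 8 libraries was left out, with an adjusted p up to 0.0868, and that of FOXC2 when any 1 of 6 was (0.0737). The enzyme list had an adjusted p of 0.16 without control replicate 4, 0.0509 without control replicate 5, 0.0637 without NSD3 morpholino replicate 1 and 0.0588 without replicate 2. It was 0.375 without control replicates 4 and 5, the highest of 24 alternatives (lowest 0.00799), with a median log2 fold change of -0.03 against -0.08 and 0 members called. The mesoderm list had 0.0812 without control replicate 3, 0.101 without NSD3 morpholino replicate 3 and 0.31 without a filter, the highest of 24 alternatives (lowest 0.0026). In all, 9 of 28 lists were called, 0 of them with an estimated correlation, and 42 of 100 splits of the libraries called as many. By fry for 1 direction, 1 of the 28 lists was called, that of p53 targets. Its mixed form, which lets genes of a list move either way, called 11. Fry's mixed adjusted p was 6.56e-05 for neural crest EMT and migration, 0.0131 for neural tube progenitors, 0.0176 for neural crest specification and 0.0188 for the neural plate border. This form does not compare a list with other genes, and 2157 of the 11935 genes tested had an unadjusted limma p under 0.05.

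**Figure D4:**
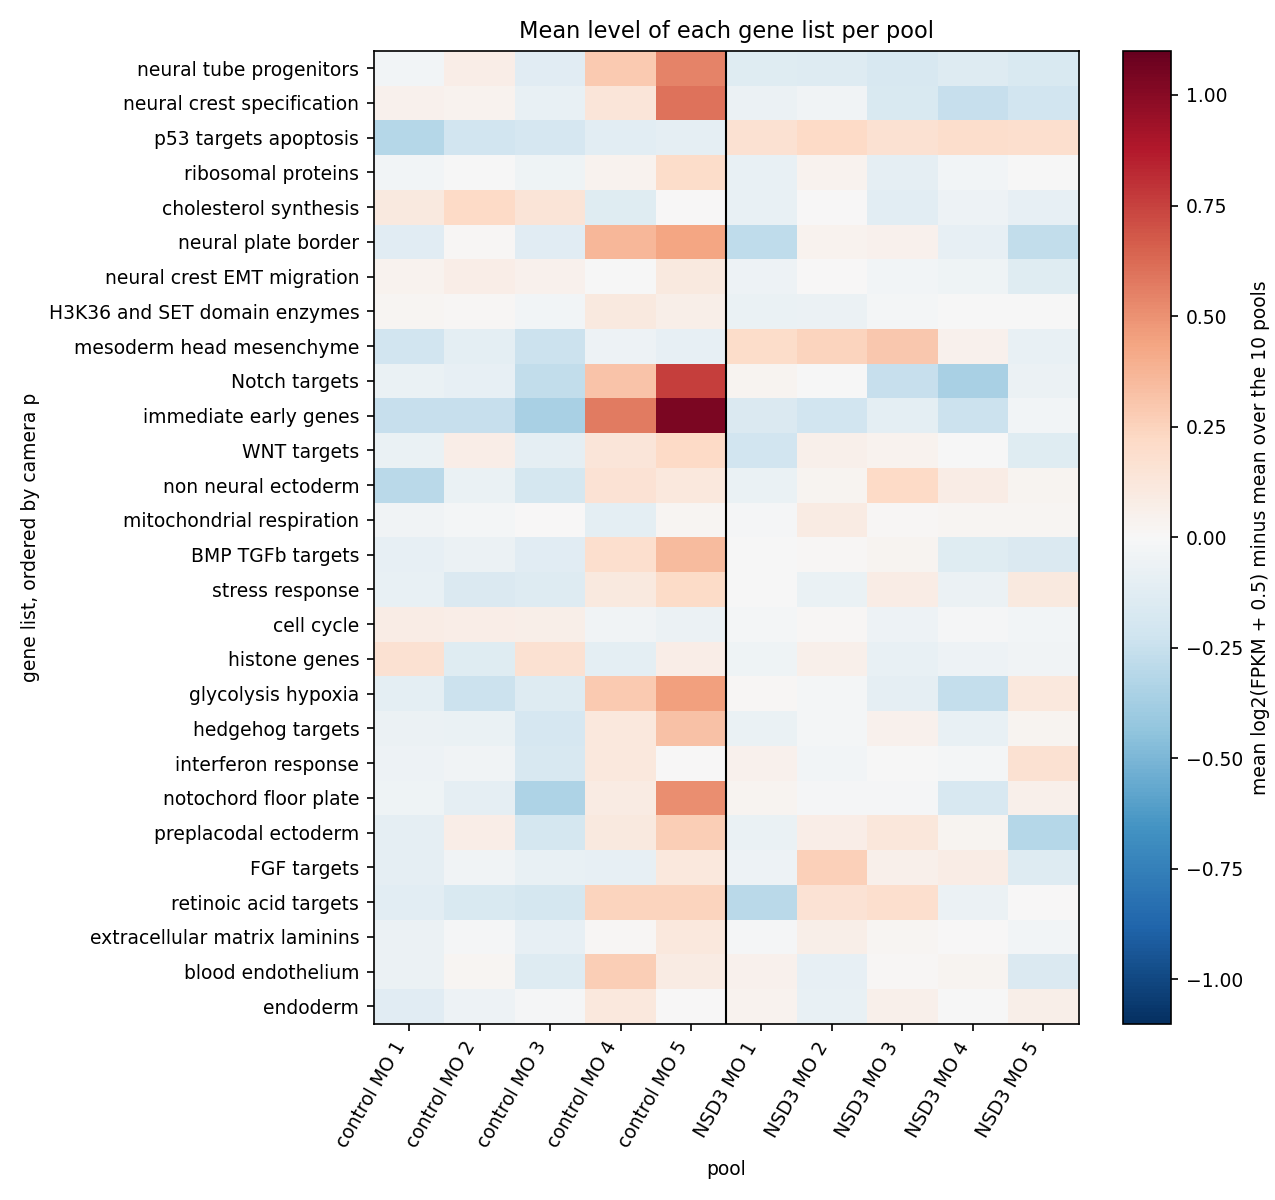
Mean level of each of the 28 tested gene lists (rows, ordered by camera p) in each pool (columns), as the mean log2(FPKM + 0.5) minus the mean over the 10 pools. The p53 list is above 0 in all 5 NSD3 morpholino pools and below 0 in all 5 control pools, and the immediate early list reaches 0.568 and 1.035 in control replicates 4 and 5.

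The libraries themselves were compared by principal components. The first component held 31.3% of the variance and set control replicates 4 and 5, at 29.9 and 37.1, apart from the other 8 libraries, which lay between -14.6 and 1.04. On the second component, with 19.3% of the variance, all 5 NSD3 morpholino pools lay below all 5 control pools. FOS, an immediate early gene, stood at 22.2 and 63.5 FPKM in control replicates 4 and 5, and between 2.21 and 6.05 FPKM in the other pools. JUN stood at 136 and 170 FPKM there, and between 13.3 and 46.2 FPKM in the others. Spearman correlations between libraries ran from 0.956 to 0.989 within controls and from 0.982 to 0.989 within the NSD3 morpholino group. Between the groups they ran from 0.9613 to 0.9853. The between-group median of 0.9746 was above the median of 0.9724 within controls and below that of 0.9853 within the NSD3 morpholino group. Control replicates 4 and 5 correlated with control replicates 1 to 3 at 0.9564 to 0.9733. Control replicates 1 to 3 correlated with the NSD3 morpholino pools at 0.9731 to 0.9853.

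The comparison was set beside the authors' deposited table, which lists 358 genes higher and 316 lower. Of these 674 genes 609 were tested here, and all 609 had the same direction of change. The calls shared 157 genes higher and 114 lower, 271 in all, with 0 in opposite directions, while independent lists of these sizes would share 4.78 and 2.96. Another 30 genes were called here but are not in the authors' deposited table. Both rest on the same libraries, so the overlap is not independent evidence. The largest change in the authors' deposited table among genes named here was that of NYX, with a log2 fold change of -4.18 there.

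The authors' deposited table also marks which of its genes belong to neural crest classes of another published data set. Of 68 genes in the class raised in premigratory neural crest, among them SOX9, TFAP2B, EN1 and ZIC1, 46 were lower in the authors' deposited table (67.6%), against 44.6% of the other genes (Fisher's exact test, p 0.000311, adjusted over 4 classes 0.00117). The other 22 genes of this class were higher. Their log2 fold changes reached 4.18 there, while the largest fall in the class was -1.46. Of 30 genes in the class reduced in premigratory neural crest, which holds ACTC1 and FOXC2, 5 were lower (16.7% against 48.3%, exact p 0.000586, adjusted 0.00117). Of 21 genes reduced in migratory neural crest 16 were lower (exact p 0.00715, adjusted 0.00953), and of 3 genes raised there 2 were lower (exact p 0.603). Genes are not independent replicates, and these genes were chosen for their change in the same libraries. Control replicates 4 and 5, whose neural crest specification list levels of 0.136 and 0.599 were the highest of the 10 pools, are among these libraries, and the class counts were not repeated without them.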

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

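The tests of explanations in this part were chosen after the results were seen. Among 140 groups of 5 values examined, 12 held a value far from the other 4, where chance alone gives about 5%.

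Control replicate 5 held the highest control value of several genes: NYX at 17.4 FPKM against at most 10.1 in the other controls, COQ9 at 15.4 against 12.8, TFAP2B at 81.9 against 58.5, FOXD3 at 731 against 347 and SOX10 at 32.2 against 14.8. EN1 was low in control replicate 3, at 5.74 FPKM against at least 9.35. HINTW, a gene of the female-specific W chromosome, was low in control replicate 2, at 90.2 FPKM against at least 270.0. In the NSD3 morpholino group, JUN was high in replicate 5, at 46.2 FPKM against at most 24.2, and MSX1 in replicate 2, at 316 against 245. In replicate 1 of that group, EDA2R was low at 11.9 FPKM against at least 13.9, DLL1 was high at 11.7 against 8.73, and relative depth was high at 1.295 against 0.972.

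Control replicates 4 and 5 stood apart on the first principal component. For depth, 0 of these 2 libraries lay outside the relative depth range of the other 8, but the upper end of that range rests on 1 library. That library was NSD3 morpholino replicate 1, at 1.295. Control replicates 4 and 5, at 1.055 and 1.018, came next, above control replicate 1 at 1.011. Even so, NSD3 morpholino replicate 1 and control replicate 1 lay at -13.07 and -6.33 on this component, which argues against depth as read from the FPKM steps. For the sex make-up of the pools, a first test on HINTW put 1 of these 2 libraries outside the range of the other 8, with control replicate 4 at 292.7 FPKM against 290.5 in control replicate 1. After that outcome was seen the test was replaced by the W-linked list mean, where 0 of them lay outside, so sex make-up is argued against by the later test and cannot be told apart by the first. A tissue handling response in these pools may be behind it, since their immediate early list means lay at least 0.598 above the other 8 libraries on the log2 scale, and a difference in stage was not tested.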

How the results depend on the processing

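The alternatives without control replicates 4 and 5 and with covariates were chosen after the data were seen. Counts of genes higher and lower, 179 and 122 in the main comparison, were 344 and 207 with array quality weights, 55 and 20 at an adjusted p under 0.01, 391 and 286 with the immediate early covariate and 75 and 43 with the W-linked covariate. Leaving out 1 library gave 69 to 211 higher and 32 to 151 lower, the lowest without NSD3 morpholino replicate 2. Without control replicates 4 and 5 the counts were 202 and 145, of which 185 genes were shared with the main calls. With the replicate number as a block the counts were 97 and 62. The counts under the remaining settings stayed within 1.5 times. The causes were not tested, except that a stricter threshold leaves fewer calls by construction. The main model, fixed before the data were examined, had no block. Deviations of same-numbered libraries correlated at 0.214, -0.035, -0.128, -0.065 and 0.34 for replicates 1 to 5, so pairing by number is neither shown nor excluded. NSD3 stayed lower in all 24 alternatives, with log2 fold changes from -0.392 to -0.243 and adjusted p from 0.0335 to 0.169. It passed the threshold with a minimum mean FPKM of 5 (-0.343), with rescaling to the same total (-0.392) and with the immediate early covariate (-0.278). The lists of p53 targets and of cholesterol synthesis were called in 24 of 24 alternatives with the preset correlation. In the main comparison neither was called with an estimated correlation (adjusted p = 0.0736 and 0.589), the estimates being 4e-04 and 0.1831. Without control replicates 4 and 5 the glycolysis and hypoxia list turned to a median log2 fold change of 0.1309 (adjusted p 0.0392, up to 0.877 elsewhere), and adjusted p = 0.549 with an estimated correlation. Other lists that were not called in either setting, such as immediate early genes and Notch targets, changed sign there too. Of 47 called genes named by the rule or afterwards, 23 kept their call in every alternative at the 0.05 threshold that tested them and 0 reversed, while SOX9 lost its call in 12 of 24. At an adjusted p under 0.01 in the authors' deposited table, 263 genes were shared instead of 271. Recovery of changes of 0.5 on the log2 scale was 56% in simulated data, so smaller changes can be missed.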

Other observations

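The tests of explanations and of other splits in this part were chosen after the results were seen. Outside the lists called by camera, several single genes moved. BNIP3, a mitophagy receptor gene, rose from 22.4 ± 2.75 to 31.7 ± 1.29 FPKM, while PFKP, a phosphofructokinase gene, fell from 22.4 ± 1.55 to 17.1 ± 1.08 FPKM, the 2 called members of 28 in the glycolysis and hypoxia list (camera adjusted p 0.552). XBP1, a transcription factor gene of the unfolded protein response, fell from 95.4 ± 8.95 to 69.0 ± 7.98 FPKM, 1 of 27 in the stress response list (adjusted p 0.267). CDON, a hedgehog co-receptor gene, fell from 46.7 ± 4.47 to 34.6 ± 4.96 FPKM, 1 of 9 hedgehog targets (adjusted p 0.636), whose median was 0.04 while the mean was -0.04. HELZ2 fell from 7.08 ± 1.27 to 4.86 ± 0.326 FPKM, 1 of 14 interferon response genes (adjusted p 0.659). The call of CDON ended when any 1 of 8 libraries was left out, with an adjusted p up to 0.109, that of HELZ2 when any 1 of 9 was (0.112), and those of PFKP and XBP1 when any 1 of 4 was (0.0637 and 0.0662).

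Among the other tested lists no gene was called over all genes, and their camera adjusted p were 0.0518 for Notch targets, 0.0759 for immediate early genes, 0.0792 each for WNT targets, non-neural ectoderm and mitochondrial respiration, 0.25 for BMP and TGFb targets and 0.267 for cell cycle. Values were 0.528 for histone genes, 0.666 for notochord and floor plate, 0.669 for preplacodal ectoderm, 0.759 for FGF targets, 0.78 for retinoic acid targets, 0.94 for blood and endothelium and 0.948 for endoderm, whose median was -0.03 while the mean was 0.03. Adjusted over the list alone, 2 genes rose in non-neural ectoderm and 1 in endoderm, 1 fell among Notch targets and 2 among BMP and TGFb targets, and 1 rose and 2 fell among FGF targets, with 0 in the other lists of this paragraph. Adjusted over the list alone, 1 rose and 1 fell in each of the glycolysis and stress lists, 2 fell among hedgehog targets, and 1 rose and 2 fell among interferon genes. With the preset correlation, Notch targets were called in 10 of 24 alternatives (lowest adjusted p 0.00634), non-neural ectoderm in 7, mitochondrial respiration in 5, immediate early genes and WNT targets in 4 each and cell cycle in 2. In the main comparison each of these 6 had adjusted p = 0.759 with an estimated correlation. The cell cycle list without control replicates 4 and 5 had a median log2 fold change of -0.09 and an adjusted p of 0.0315, and adjusted p = 0.229 with an estimated correlation. Of HOX genes and of W-linked genes 3 each were tested, too few for the list test, and none was called. HINTW averaged 245 ± 87.3 and 191 ± 59.9 FPKM (limma adjusted p 0.677).

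The counts of genes were set against other splits of the libraries. The real split gave 179 and 122 calls, and no other of the 100 splits drawn gave more than 1 in either direction. For both counts 1 of 100 was as large, the smallest share that 100 splits can give. Other splits mix the 2 groups, so a group difference widens the spread within them and lowers their counts. Chance is therefore argued against for both counts but not excluded. The count of lists is different: the real split called 9 lists, 42 of 100 splits called as many, and the highest other called 19, so chance cannot be excluded for the number of lists. For the p53 target list, whose camera p was 0.000185, 1 of 100 splits gave as small a p, the lowest other being 0.00389. For neural tube progenitors (p 1.06e-06) and neural crest specification (p 1.07e-05), 13 of 100 splits each gave as small a p, the lowest others being 5.95e-10 and 1.4e-09, so chance cannot be excluded for these 2.

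For the rise of p53 target genes, handling stress that differed between the pools is argued against as the whole cause. The stress meant is the kind that raises immediate early genes. Control replicates 4 and 5 had the highest immediate early levels but p53 list levels of -0.119 and -0.1, under the 0.165 or more of the NSD3 morpholino pools. Those 2 levels were still the highest among the controls, where the others lay between -0.315 and -0.187. CDKN1A was highest there too, at 3.284 and 3.995 FPKM against at most 2.272 in the other controls. A smaller part of handling stress in the p53 levels is therefore not excluded. With the immediate early covariate 9 list members were called higher against 7 without it, but calls among all genes increased too. Scaling of the deposited values is argued against as well, since 7 members were called with rescaling to the same total and 7 with quantile normalization. Rescaling by median ratios changed none of the 301 calls, so it decides nothing here. An effect of the NSD3 morpholino other than loss of NSD3 cannot be told apart from loss of NSD3, because the design holds 1 NSD3 morpholino and no rescue. Activation of p53 is a known side effect of morpholinos in zebrafish and may apply here, and loss of NSD3 itself may equally raise these genes.

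For the lower neural crest and neural tube genes, control replicates 4 and 5 raise the control mean and may account for part of the shift of the lists, since 0 of the 3 lists of neural tube progenitors, neural crest specification and neural plate border stayed called without them. Their median log2 fold changes went from -0.24 to -0.10, from -0.21 to -0.12 and from -0.18 to -0.02. For the 8 members called lower in these lists and in the neural crest EMT and migration list, the median log2 fold change was -0.609 without them against -0.675 with them and ZIC1, TFAP2B and NCAM1 kept their call, but the part of control replicates 4 and 5 cannot be told apart because the 8 were picked with them included. A smaller share of neural cells in the NSD3 morpholino pools cannot be told apart from a change in the cells for the called members, because the 18 of 29 neural tube members with a 95% interval above -0.675 are set against genes picked as lower. It cannot be told apart for the lists either, since 1 of 5 lists of other tissues, that of mesoderm, was higher (adjusted p = 0.589 with an estimated correlation) and 0 were lower, and without control replicates 4 and 5 the non-neural ectoderm list was higher too (adjusted p 0.000759, up to 0.498 in other alternatives, and adjusted p = 0.396 with an estimated correlation), and loss of NSD3 remains open.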
